A study of Thermococcus paralvinellae with 15 samples.

How the data were processed

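Messenger RNA of Thermococcus paralvinellae, a heat-loving archaeon, was sequenced in 15 libraries from 5 growth conditions with 3 libraries each. The conditions were maltose, maltose with hydrogen, tryptone, tryptone with hydrogen, and formate. Per the labels, total RNA was extracted with TRIzol and a column kit, ribosomal RNA was removed, and paired ends were read on a HiSeq2500. Per the submitters' processing notes, reads were handled with CASAVA, STAR 2.5.1b and featureCounts. The strand setting, the treatment of reads matching several genes and the genome build are not given in the sources used here. The labels number the replicates but do not say whether they are separate cultures, so p-values measure only the spread between these libraries.

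The deposited count table holds whole read counts per gene, not normalised, for 2083 genes. The deposited TPM table holds values computed from the same counts by coding length, since the ratio of count to TPM per gene was proportional across libraries. Totals ran from 4512358 to 15608822 counts per library. The files hold no rRNA or tRNA genes, although the reference lists 50. The lowest count of any gene in any library was 3, so no gene was undetected.

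Genes were named through a RefSeq gene table of assembly ASM51744v1, which was used only for names and for which genes neighbour each other. Locus tags matched for 2012 genes and symbols for 42. Of the 2083 genes, 339 have a symbol, and 313 of them were given a product name from a table written by hand from the symbols, so most genes are identified only by locus tag. The symbol hycE covers the summed counts of 3 genes, porA of 2 and tfb of 2, because the deposited tables give 1 line per symbol. Reads of near-identical copies, of overlapping genes and of antisense genes cannot be told apart here.

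Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test with robust dispersion, TMM scaling and its expression filter, which all 2083 genes passed. All 15 libraries entered 1 fit with 5 group means and 10 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and an adjusted p under 0.05 counted as changed. The biological coefficient of variation was 26.0%. Log2 fold changes are given with approximate standard errors (SE). Each SE is the absolute log2 fold change divided by the square root of its F statistic, so it adds nothing to the test. Levels are TMM-scaled CPM as mean ± SD of 3 libraries.

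Gene lists were written as word patterns on these hand-written product names, so function lists draw on 313 of the 2083 genes. Lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists tested per comparison. There were 21 function lists: hydrogenase, formate, hydrogenase maturation, cation/proton antiporter, 2-oxoacid oxidoreductase, glycolysis and gluconeogenesis, amino acid biosynthesis, amino group transfer, peptidase, cofactor biosynthesis, nucleotide biosynthesis, sulfur and iron-sulfur, metal transport, ribosomal protein, RNA polymerase, aminoacyl-tRNA synthetase, chaperone and proteasome, transcription regulator, DNA replication and repair, CRISPR, and mobile and toxin. The other 10 lists were gene runs: neighbouring genes with gaps of at most 100 bp around a hydrogenase, formate or antiporter gene, or around the carbon monoxide dehydrogenase gene cooS. Strand is not in the reference table and was not used. The hydrogenase list holds shyA, shyB, shyC, shyD, nuoI, both mbhE genes and hycE. The formate list holds both fdhF genes, fdhD and hycE. All of these but the summed hycE are also members of the gene runs, so these function lists are not results separate from the runs. Each list was tested again with a correlation estimated from its own genes, and with fry. Product names for symbols, and a few word exclusions, were set once the gene names were known and before any test. The seeds of the runs were written after a first exploratory fit had been seen.

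The comparisons, tests, word patterns and first set of other settings were fixed before the data were examined. So was the rule for naming genes: in each comparison the 6 largest rises and 6 largest falls among changed genes with a product name, a mean log2 CPM of at least 4 and group ranges that do not overlap. All members of the hydrogenase, formate and hydrogenase maturation lists could be named too, and up to 4 members with the smallest p of any other list described. Up to 2 rises and 2 falls among genes without a symbol were added afterwards because most genes have none. Which of these genes had their alternatives examined 1 by 1 was narrowed to those printed here after the values were seen.

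The other settings tried were DESeq2 size factors in edgeR, library totals without TMM, no filter, a stricter filter, the replicate number as a block, only the groups compared, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), a 2-fold minimum, and leaving out each library in turn. A fit without tryptone replicate 1 for every comparison and voom with library quality weights were added after the data had been seen. Voom's weight was 0.038 for tryptone replicate 1, against 5.769 and 3.265 for tryptone replicates 2 and 3. For comparisons with tryptone it is therefore not separate from the fit without that library. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

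The fit was tested on simulated counts with 200 genes changed by known amounts. Of 4-fold changes, 100% were recovered for maltose with hydrogen, 97.2% for tryptone with hydrogen, 76.8% for the difference of the hydrogen responses, 92.2% for tryptone against maltose, 96.4% for formate against maltose and 95.4% for formate against tryptone. Of 1.5-fold changes, 11.1%, 25%, 0%, 21.1%, 21.7% and 17.1% were recovered in the same order, so small changes are mostly missed at this replication. Between 3 and 11 unchanged genes were called per comparison. The simulated genes varied independently and no simulated library was set apart from its group. Recovery in the real counts may therefore differ.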

Results

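The transcriptome of Thermococcus paralvinellae, a hyperthermophilic archaeon that releases hydrogen when it ferments sugars and peptides, was measured under 5 growth conditions. The series asks how the cells respond to hydrogen stress. Cells grew on maltose or on tryptone, each without and with hydrogen, or on formate, and 3 libraries were sequenced per condition. Total counts of replicates 1 to 3 were 13562105, 15608822 and 11001844 on maltose, and 15039562, 14675044 and 13943708 on maltose with hydrogen. They were 8612235, 12209422 and 14151086 on tryptone and 12451974, 12463542 and 14278518 on tryptone with hydrogen. Formate libraries were the shallowest, with 6222640, 4512358 and 7456028.

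Formate libraries lay apart from all others along the first principal component. They shared 1 feature with tryptone replicate 1: the 10 genes with the most counts took 26.46% to 34.18% of counts on formate and 26.89% in that tryptone library, against 11.99% to 17.68% elsewhere. Tryptone replicate 1 correlated with tryptone replicates 2 and 3 at 0.855 to 0.896 across genes, while those 2 correlated at 0.991; genes are not independent replicates. Counts of changed genes in comparisons that use tryptone are therefore also given without that library. With library totals in place of TMM, the median gene moved by -0.16 with hydrogen on maltose, 0.40 with hydrogen on tryptone, 0.51 in the difference of these responses, -0.11 on tryptone against maltose, -1.31 on formate against maltose and -1.15 on formate against tryptone. On the TPM scale those medians were -0.19, 0.53, 0.67, -0.34, -1.20 and -0.88, and all folds below are relative to the TMM scale.

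**Figure D1:**
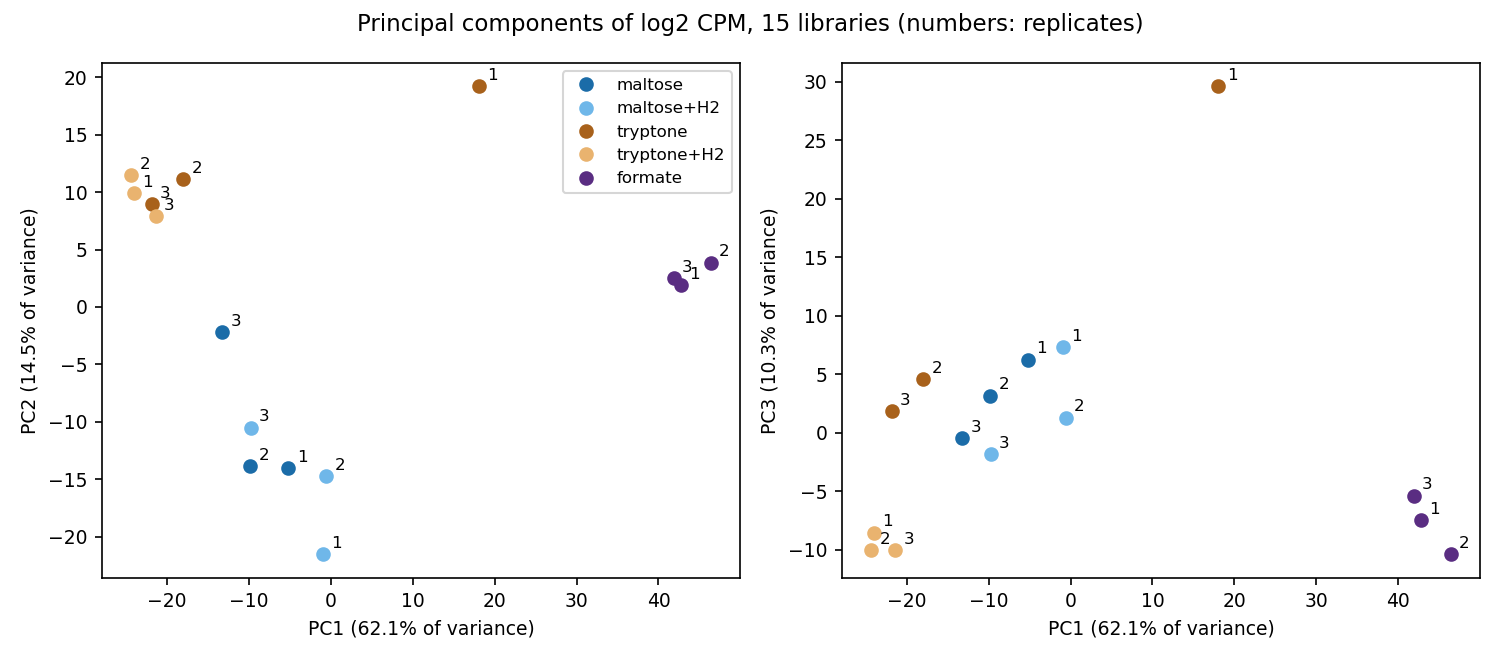
Principal components of log2 CPM for the 15 libraries, PC1 against PC2 and PC1 against PC3, with the share of variance on each axis, colours for the 5 conditions and numbers for replicates. PC1 holds 62.1% of the variance, PC2 14.5% and PC3 10.3%, and tryptone replicate 1 lies away from tryptone replicates 2 and 3.

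With hydrogen on maltose, the transcript of a formate dehydrogenase alpha subunit rose most among named genes. This enzyme subunit oxidises formate, and its gene fdhF (TES1_RS07825) went from 1220 ± 479 to 12600 ± 4774 CPM (10.3-fold, log2 fold change 3.37 ± 0.58 SE, adjusted p = 0.01735). The next gene, TES1_RS07820, rose 10.8-fold, from 336 ± 124 to 3629 ± 1321 CPM (adjusted p = 0.01735). TES1_RS07775 rose 9.8-fold (adjusted p = 0.02861), and TES1_RS07780 and TES1_RS07790 rose by log2 2.57 ± 0.44 and 2.61 ± 0.44. All of these lie in the run of 17 measured genes from TES1_RS07740 to TES1_RS07825, which also holds an antiporter subunit. The symbol hycE, the large subunit of a formate hydrogenlyase-type hydrogenase, sums TES1_RS07795 of this run with TES1_RS00505 and TES1_RS06340 of 2 other runs, so its changes cannot be placed in any 1 of them. Of the run's 17 genes 6 rose, 0 fell and 11 did not pass, and 17 rose when adjusted over the list alone. The run's median was 1.82 (camera adjusted p = 4.474e-39; adjusted p = 0.07019 with an estimated correlation). The summed hycE, at 3040 ± 383 against 1028 ± 342 CPM, did not pass (1.56 ± 0.36, adjusted p = 0.08707). It passed without tryptone replicate 1 (1.56, adjusted p = 0.008799), with DESeq2 (1.52, 2.39e-04), library totals (1.38, 0.02586), limma on TPM (1.42, 0.008199) and voom (1.72, 3.542e-04).

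Only 1 gene fell with hydrogen on maltose, TES1_RS08035, from 855 ± 247 to 275 ± 21.7 CPM (-1.64 ± 0.25, adjusted p = 0.01735). The soluble hydrogenase genes shyB, shyC, shyD and shyA did not pass (0 of 4, 0 adjusted over the list alone), with shyC at 147 ± 27.1 against 177 ± 45.0 CPM (-0.27 ± 0.18, adjusted p = 0.6637). The second fdhF (TES1_RS00480) did not pass either, at 254 ± 60.2 against 306 ± 87.0 CPM (adjusted p = 0.8805). Its run of 16 genes had 0 past (0 adjusted over the list alone) and a median of -0.43 (camera adjusted p = 0.0107; adjusted p = 0.8894 with an estimated correlation). Ribosomal protein genes leaned up, with 0 of 24 past (0 adjusted over the list alone) and a median of 0.76 (camera adjusted p = 2.719e-07; adjusted p = 0.8894 with an estimated correlation). The formate list had 1 of 4 genes up (2 adjusted over the list alone; camera adjusted p = 0.004935, and adjusted p = 0.08158 with an estimated correlation). Of the 31 lists, 3 passed upward and 4 downward, and 0 passed with an estimated correlation. Only 4 lists passed without maltose replicate 3, and 4 without replicate 1 with hydrogen. The 4 downward lists were amino acid biosynthesis and the runs of fdhF TES1_RS00480, mbhE TES1_RS07645 and mnhG TES1_RS07205. All 4 lost their calls in both of these fits and with library totals. With library totals camera's adjusted p was 0.09942 for amino acid biosynthesis, 0.1274 for the mbhE run and 0.185 for the mnhG run. The call of the run of TES1_RS00480 was lost with library totals (median -0.56, adjusted p = 0.1802), without maltose replicate 2 (adjusted p = 0.124), without maltose replicate 3 (0.235), without replicate 1 with hydrogen (0.2047) and without replicate 2 with hydrogen (0.1489).

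In total 7 of 2083 genes changed with hydrogen on maltose, 6 up and 1 down (edgeR, adjusted p under 0.05). The split was 20 up and 11 down with library totals, 54 up and 32 down with DESeq2, and 18 up and 8 down with limma on TPM. This small count moved when single libraries were left out. It was 0 without maltose replicate 1 (267 genes at an unadjusted p under 0.05), 1 without maltose replicate 2, 0 without replicate 2 with hydrogen (193 genes unadjusted), 16 without maltose replicate 3 and 23 without replicate 3 with hydrogen. Without tryptone replicate 1, which enters only through the shared spread, it was 74, and 16 genes of the TES1_RS07825 run rose. The biological coefficient of variation in that fit was 19.1%, against 26.0% with all libraries. With only the groups compared the count was 9, with 7 up and 2 down. The adjusted p of fdhF (TES1_RS07825) was 0.1853 without maltose replicate 1, 0.1214 without maltose replicate 2 and 0.05276 without replicate 2 with hydrogen. Its log2 fold changes in these fits stayed close to that with all libraries, at 3.259, 3.174 and 3.537. The other genes named as changed lost their calls with fdhF, except that TES1_RS08035 kept its call without maltose replicate 2. TES1_RS07775 also lost its call without maltose replicate 3 (0.05211) and with the replicate number as a block (3.226, 0.06417).

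With hydrogen on tryptone, the same neighbourhood was higher. TES1_RS07790 rose 3.4-fold (1.77 ± 0.43, adjusted p = 0.0395), and TES1_RS07785, TES1_RS07780 and TES1_RS07770 rose by log2 1.70, 1.74 and 1.27. The summed hycE, of 3 runs, rose 2.71-fold, from 1623 ± 485 to 4397 ± 471 CPM (1.44 ± 0.36, adjusted p = 0.0447). The fdhF gene TES1_RS07825 stood at 10780 ± 703 against 3150 ± 2403 CPM and did not pass (1.78 ± 0.55, adjusted p = 0.08081). It passed without tryptone replicate 1 (2.58, adjusted p = 0.007324), with DESeq2 (1.83, 0.008588), library totals (6.75e-04), limma on TPM (2.61, 4.93e-05) and voom (2.48, 5.038e-05). Of the run's 17 genes 5 rose, 0 fell and 12 did not pass, and 16 rose when adjusted over the list alone. Its median was 1.67 (camera adjusted p = 9.595e-15; adjusted p = 0.5399 with an estimated correlation), and without tryptone replicate 1 the median was 2.32 and 13 genes rose. The calls of hycE and of the 4 single genes were lost without tryptone replicate 2, with log2 fold changes of 1.345 for hycE (adjusted p = 0.06667) and 1.60 for TES1_RS07790 (0.0626). The same 5 calls were lost with the replicate number as a block, with 1.427 for hycE (0.07696) and 1.794 for TES1_RS07790 (0.06999). The genes shyBCDA had 0 of 4 past (0 adjusted over the list alone; median 0.07; adjusted p = 0.8336 with an estimated correlation).

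Several cobalamin genes fell with hydrogen on tryptone. The synthase gene cbiB fell 5.3-fold, from 790 ± 719 to 149 ± 34.2 CPM (-2.40 ± 0.46, adjusted p = 0.02645). Another cobalamin gene, cobS, fell from 871 ± 758 to 195 ± 13.9 CPM, and cobZ and cobT fell too (log2 fold changes -2.14 and -1.80). Of these genes cobS is not a member of the cofactor biosynthesis list, here or in the other comparisons. Cofactor biosynthesis as a list had 3 of 16 down (3 adjusted over the list alone), a median of 0.03 and -0.01 without tryptone replicate 1, and did not pass (camera adjusted p = 0.7979; adjusted p = 0.8336 with an estimated correlation). The iron-sulfur assembly gene sufB fell from 4930 ± 3666 to 1082 ± 202 CPM (adjusted p = 0.0395), with sufC, the ribulose-bisphosphate carboxylase gene rbcL, the translocase gene secY, the transcription factor gene tfe, the tRNA ligase gene cysS and argH of arginine synthesis also down. Among genes with no symbol, TES1_RS05165 fell most (-2.85), then TES1_RS05170 (-2.73). The neighbourhood of cobS, TES1_RS05040 to TES1_RS05315, was singled out after the values were seen: 34 of its 56 genes fell and 0 rose, and 21 fell and 1 rose without tryptone replicate 1 (median -1.81, then -0.99). The large SDs of the tryptone group come mostly from replicate 1. Without it cbiB, cobS and cobZ still fell but by less, with log2 fold changes of -1.33, -1.16 and -1.12, as did secY (-0.93), tfe (-0.97) and argH (-0.74). In the same fit the falls of sufB (adjusted p = 0.1104), rbcL (0.05368), sufC (0.1703), cysS (0.07649), cobT (0.05368), TES1_RS05165 (0.07893) and TES1_RS05170 (0.1317) did not pass, with log2 fold changes from -0.891 for cobT to -1.744 for TES1_RS05165.

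Ribosomal protein genes had 0 of 24 past with hydrogen on tryptone, while 7 fell when adjusted over the list alone. Their median was -0.93 (camera adjusted p = 1.976e-04; adjusted p = 0.8336 with an estimated correlation), and -0.16 without tryptone replicate 1 (camera adjusted p = 0.0905). The run of 14 genes with mbhE (TES1_RS07715), a membrane-bound hydrogenase subunit, had 0 past (0 adjusted over the list alone), a median of -0.81 (adjusted p = 0.8336 with an estimated correlation) and -0.08 without tryptone replicate 1. The run of TES1_RS00480 had 0 of 16 past (0 adjusted over the list alone), a median of 0.46 (adjusted p = 0.8336 with an estimated correlation) and 0.01 without that library, and did not pass with library totals (camera adjusted p = 0.1861). In total 76 genes changed, 9 up and 67 down; the split was 22 up and 39 down with library totals, 22 up and 32 down with limma on TPM. The count was 153 without tryptone replicate 2 and 331 without tryptone replicate 3. It was 0 without replicate 1, 2 or 3 with hydrogen (347, 323 and 380 genes unadjusted), against 290 with DESeq2 on all libraries. All genes named as changed with hydrogen on tryptone lost their calls in those last 3 fits, although the folds kept their direction: hycE had 1.488, 1.346 and 1.475, cbiB -2.226, -2.511 and -2.496, and TES1_RS05165 -2.508, -2.657 and -3.629. With voom, which gave tryptone replicate 1 a weight of only 0.038, the count was 568 (284 up and 284 down), without the lean toward falls. With only the groups compared the count was 0 (275 genes unadjusted). With the replicate number as a block it was 25 (3 up and 22 down), and of the genes named here cbiB, cobS and cobZ alone kept their calls. Without tryptone replicate 1 the count was 53, with 18 up and 35 down. Of the 31 lists 7 passed, and 0 passed with an estimated correlation; 2 passed without tryptone replicate 1, 11 without replicate 1 with hydrogen and 4 without replicate 2 with hydrogen.

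Whether hydrogen acted alike on both carbon sources was tested by the overlap and by the difference of the responses. The genes TES1_RS07780, TES1_RS07785 and TES1_RS07790 of the fdhF run rose on both, 3 genes where 0.0259 were expected for unrelated lists (two-sided Fisher's exact test, p = 1.11e-06, genes not independent), and 0 genes fell on both (expected 0.0322). Across all 2083 genes the log2 fold changes had a Pearson r of 0.002 and a Spearman rho of -0.12; genes are not independent replicates. Pearson r was 0.203 without tryptone replicate 1 (Spearman rho -0.001), 0.215 with voom, and -0.095 to 0.117 without 1 of the other libraries. Shared genes numbered 0 without maltose replicate 1, maltose replicate 2, maltose with hydrogen replicate 2 or 3, tryptone replicate 2, or any replicate of tryptone with hydrogen; they numbered 5 without maltose replicate 3 and 15 without tryptone replicate 1.

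For the difference itself, edgeR called 0 genes, with 403 at an unadjusted p under 0.05, against 209 with DESeq2, 16 with library totals, 17 with limma on TPM and 219 with voom. It called 4 without maltose replicate 3, 1 without maltose with hydrogen replicate 3, and 23, 28 and 118 without tryptone replicate 1, 2 and 3. Ribosomal protein genes had the lowest list median, -1.85, with 0 of 24 past and 22 lower when adjusted over the list alone (camera adjusted p = 2.831e-10; adjusted p = 0.893 with an estimated correlation). The RNA polymerase list also holds the transcription factor genes nusG, tfb and tfe. It had 0 of 5 past, 4 lower adjusted over the list alone and a median of -1.61 (adjusted p = 0.893 with an estimated correlation). The run of fdhF TES1_RS07825 had a median of -0.41, which turned to 0.37 with library totals and 0.41 on TPM, and did not pass (0 of 17 past, 0 adjusted over the list alone; camera adjusted p = 0.314, and adjusted p = 0.893 with an estimated correlation).

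**Figure D2:**
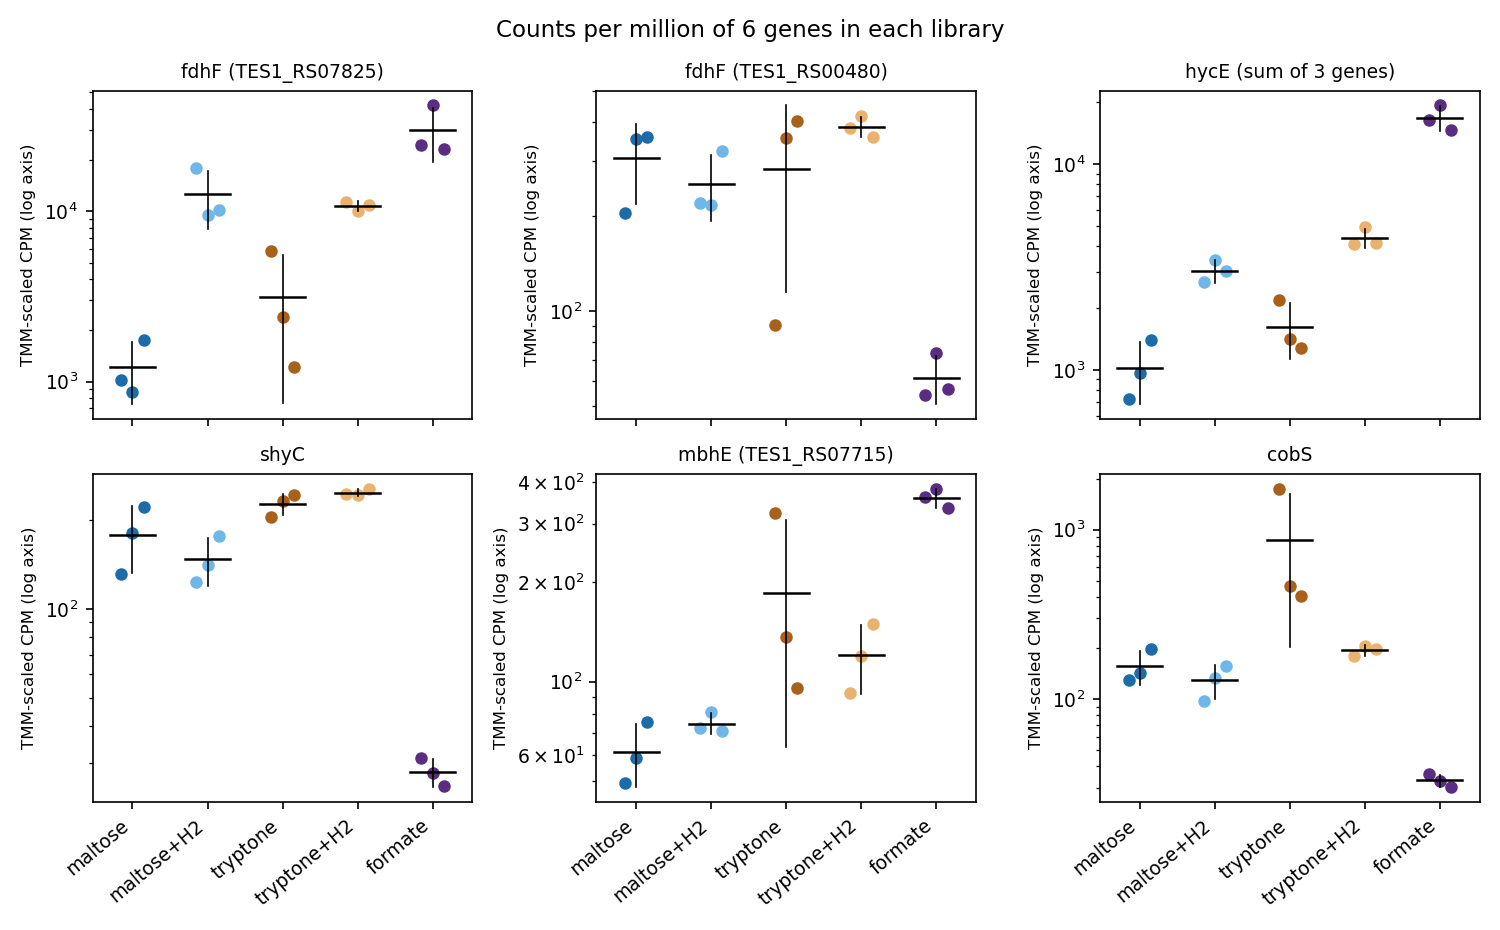
TMM-scaled CPM on a log axis for 6 genes in each library of the 5 conditions: points are libraries, horizontal lines the mean of 3 libraries and vertical bars ± SD. The fdhF gene TES1_RS07825 averaged 1220 on maltose, 12600 with hydrogen on maltose and 29880 on formate, while shyC averaged 177 on maltose and 28.1 on formate.

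Tryptone against maltose compared growth on peptides with growth on a sugar. Glycolytic genes fell: pgiA, for glucose-6-phosphate isomerase, went from 530 ± 88.0 to 195 ± 22.8 CPM (-1.44 ± 0.17, adjusted p = 2.906e-04). The phosphofructokinase gene pfkC fell (-1.05 ± 0.16, adjusted p = 0.002433), as did the aldolase gene fba (-1.45 ± 0.27, adjusted p = 0.00604). The maltodextrin phosphorylase gene malP fell from 2131 ± 242 to 919 ± 263 CPM (adjusted p = 0.01639). Its call was lost without maltose replicate 1 (0.07165), maltose replicate 2 (0.07095) or tryptone replicate 2 (0.05286). Glycolysis and gluconeogenesis had 3 of 9 genes down and 0 up, 4 down when adjusted over the list alone, and a median of -0.83 (camera adjusted p = 4.667e-07; adjusted p = 0.4223 with an estimated correlation). Without tryptone replicate 1, 8 fell and the median was -1.31. Among genes with no symbol TES1_RS06220 fell 6.46-fold and TES1_RS07285 5.49-fold; the former did not pass without maltose replicate 1 (0.07733).

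The largest rise on tryptone was in TES1_RS03685, from 182 ± 16.7 to 6553 ± 3985 CPM (36.1-fold, adjusted p = 0.005724), with its neighbour TES1_RS03690 also up (log2 fold change 4.91 ± 0.83). Both have no symbol. The arginine synthesis gene argH rose from 105 ± 19.1 to 468 ± 260 CPM (2.16 ± 0.29, adjusted p = 9.362e-04), and carA, for carbamoyl-phosphate synthase, rose 2.29-fold (adjusted p = 0.008149). The log2 fold changes of TES1_RS03685, TES1_RS03690, argH and carA were 4.56, 4.14, 1.62 and 0.92 without tryptone replicate 1. Amino acid biosynthesis had 4 of 24 up and 0 down, 4 adjusted over the list alone, with a median of 0.28 that was 0.00 on TPM (camera adjusted p = 3.174e-04; adjusted p = 0.4592 with an estimated correlation). Cobalamin genes cbiB, cobS and cobZ rose by log2 2.79, 2.47 and 2.34, and by 1.72, 1.47 and 1.32 without tryptone replicate 1. In their neighbourhood, TES1_RS05040 to TES1_RS05315, chosen after the values were seen, 43 of 56 genes rose and 0 fell (31 and 0 without tryptone replicate 1; medians 2.02 and 1.21). Of the genes there, 19 are among the 23 that stood above every other tryptone and formate library in tryptone replicate 1. Cofactor biosynthesis as a list had 3 of 16 up (3 adjusted over the list alone; median 0.14, -0.20 on TPM) and did not pass (camera adjusted p = 0.1193; adjusted p = 0.4223 with an estimated correlation). It passed without tryptone replicate 1 (median 0.43, camera adjusted p = 0.001235).

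A run of hydrogenase genes was higher on the peptides than on the sugar. The membrane-bound hydrogenase gene mbhE (TES1_RS07715) rose from 61.2 ± 13.1 to 185 ± 122 CPM (1.59 ± 0.34, adjusted p = 0.012; 0.07141 without maltose replicate 1 and 0.06147 without maltose replicate 2). Of its run of 14 genes 13 rose and 14 when adjusted over the list alone, with a median of 1.60 (camera adjusted p = 3.632e-12; adjusted p = 0.4223 with an estimated correlation). Without tryptone replicate 1, 7 rose and the median was 0.79. The fdhD run had 4 of 5 genes up, 5 adjusted over the list alone (median 1.42; adjusted p = 0.4223 with an estimated correlation). Of these 5, 3 rose without tryptone replicate 1, with a median of 0.87. The run of fdhF TES1_RS07825 had 0 of 17 past and 13 up adjusted over the list alone (median 1.11, 0.57 without tryptone replicate 1; adjusted p = 0.4592 with an estimated correlation). The 8 hydrogenase genes had 1 up, 3 adjusted over the list alone, and a median of 0.44 (camera adjusted p = 0.00515; adjusted p = 0.4592 with an estimated correlation). That list did not pass with library totals (median 0.33, camera adjusted p = 0.07619).

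In total 163 genes changed between tryptone and maltose, 119 up and 44 down; the split was 92 up and 90 down with library totals, and 83 up and 118 down with limma on TPM. The count was 53 without maltose replicate 1, 41 without maltose replicate 2, and 1081 with voom (511 up and 570 down). With only the groups compared it was 6 (4 up and 2 down, 300 genes unadjusted), and of the genes named here pgiA, TES1_RS03685 and TES1_RS03690 alone kept their calls. The folds of the others stayed close there, such as 2.715 for cbiB (adjusted p = 0.1338), -1.489 for fba (0.1338) and 1.53 for mbhE TES1_RS07715 (0.181). Without tryptone replicate 1 it was 220, with 97 up and 123 down. Of the 31 lists 9 passed, 8 up and 1 down, and 0 passed with an estimated correlation; without tryptone replicate 1, 16 passed.

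Formate against maltose asked which genes serve growth on formate. The run of fdhF TES1_RS07825 rose as a whole. Its alpha subunit gene went from 1220 ± 479 to 29880 ± 10470 CPM (24.5-fold, 4.61 ± 0.62, adjusted p = 6.479e-05). The summed hycE, of 3 runs, rose from 1028 ± 342 to 16830 ± 2355 CPM (4.03 ± 0.40, adjusted p = 5.718e-06). The antiporter subunit gene mnhG (TES1_RS07765) rose 17.4-fold, and TES1_RS07775 rose 87.6-fold, from 606 ± 129 to 53110 ± 17170 CPM. All 17 measured genes of the run rose (17 adjusted over the list alone), with a median of 5.00 (camera adjusted p = 6.276e-21; adjusted p = 0.1705 with an estimated correlation).

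The other formate dehydrogenase run went down. Its fdhF (TES1_RS00480) fell from 306 ± 87.0 to 61.3 ± 10.6 CPM (-2.33 ± 0.42, adjusted p = 4.333e-04), and mnhG (TES1_RS00530) fell 6.26-fold. All 16 genes of that run fell (16 adjusted over the list alone; median -2.35, adjusted p = 0.6422 with an estimated correlation). The soluble hydrogenase, which exchanges electrons between hydrogen and NADPH, fell too. The gene shyC went from 177 ± 45.0 to 28.1 ± 3.07 CPM (-2.66 ± 0.21, adjusted p = 1.436e-06), and shyB, shyD and shyA fell with it (-2.28, -2.23 and -1.86). All 4 passed adjusted over the list alone (median -2.26; camera adjusted p = 9.985e-08; adjusted p = 0.1705 with an estimated correlation). Next to them TES1_RS00835 fell 11.8-fold and gltA (TES1_RS00830), a glutamate synthase, fell from 410 ± 69.6 to 82.7 ± 12.2 CPM.

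Membrane-bound hydrogenase runs went opposite ways on formate. The mbhE gene TES1_RS07715 rose from 61.2 ± 13.1 to 359 ± 23.8 CPM (2.55 ± 0.35, adjusted p = 8.274e-05), and all 14 genes of its run rose (14 adjusted over the list alone; median 2.44, adjusted p = 0.5203 with an estimated correlation). The mbhE gene TES1_RS07645 fell 1.87-fold (adjusted p = 0.006561). Of its run of 21 genes 12 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.90, adjusted p = 0.6053 with an estimated correlation). The run of 14 genes with nuoI, an oxidoreductase subunit, had 13 up (13 adjusted over the list alone; median 2.54, adjusted p = 0.617 with an estimated correlation), nuoI itself by 5.53-fold. The fdhD run had 5 of 5 up (5 adjusted over the list alone), with a median of 0.98 that turned to -0.42 with library totals and -0.31 on TPM (adjusted p = 0.7792 with an estimated correlation). The cooS run had 4 of 6 down (4 adjusted over the list alone; median -0.78, adjusted p = 0.5203 with an estimated correlation). The run of mnhG TES1_RS07205 had 7 of 9 down (7 adjusted over the list alone; median -0.55, adjusted p = 0.7915 with an estimated correlation). The run of mnhG TES1_RS06320 had 2 up and 4 down of 12 (2 and 3 adjusted over the list alone; median -0.35, adjusted p = 0.8482 with an estimated correlation).

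As function lists, hydrogenase genes had 3 of 8 up and 5 down (3 and 5 adjusted over the list alone) and did not pass (median -1.38; camera adjusted p = 0.08125; adjusted p = 0.6747 with an estimated correlation). Formate genes had 3 of 4 up and 1 down (3 and 1 adjusted over the list alone; adjusted p = 0.5143 with an estimated correlation). Hydrogenase maturation genes had 3 of 5 up (3 adjusted over the list alone; adjusted p = 0.7915 with an estimated correlation), with a median of 0.75 that turned to -0.65 with library totals and -0.52 on TPM. Of these hypF rose 2.29-fold (adjusted p = 0.00798), a rise that turned to -0.26 with library totals and did not pass without formate replicate 2 (0.05761).

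**Figure D3:**
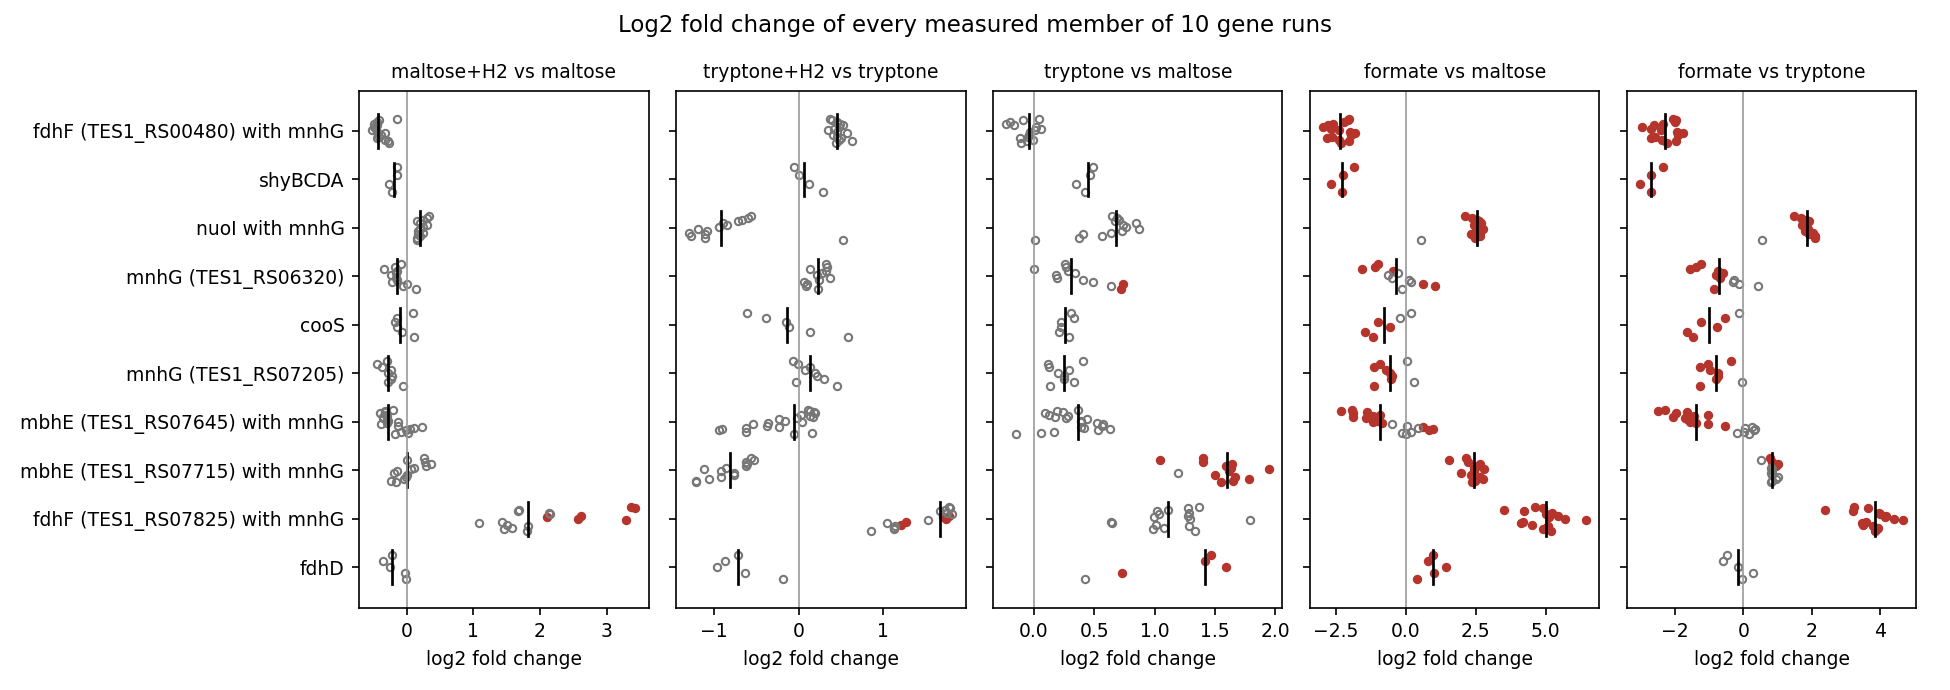
Log2 fold change of every measured member of 10 gene runs in 5 comparisons: filled points passed an adjusted p of 0.05, open points did not, and black ticks are run medians. On formate against maltose the run of fdhF TES1_RS07825 has a median of 5.00 and the run of fdhF TES1_RS00480 of -2.35.

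The riboflavin genes ribH and ribD rose on formate. The lumazine synthase gene ribH went from 82.4 ± 13.5 to 961 ± 779 CPM (3.55 ± 0.50, adjusted p = 9.977e-05) and ribD from 229 ± 70.2 to 1987 ± 1106 CPM. Cofactor biosynthesis had 3 of 16 up and 11 down, the same when adjusted over the list alone, and did not pass (median -1.03, camera adjusted p = 0.1001; adjusted p = 0.3956 with an estimated correlation). It passed without tryptone replicate 1 (camera adjusted p = 0.0265), which enters only through the shared spread. The gene cobS, which is not in that list, fell 4.75-fold. The pyruvate ferredoxin oxidoreductase gene porB, which makes acetyl-CoA, rose from 2538 ± 311 to 16610 ± 4667 CPM (2.71 ± 0.56, adjusted p = 0.001147), and porD rose 5.99-fold. The 2-oxoacid oxidoreductase list had 4 of 6 up (4 adjusted over the list alone; median 2.30, adjusted p = 0.7792 with an estimated correlation). The sugar genes pfkC and pgiA fell (-1.55 ± 0.16 and -1.34 ± 0.17). Glycolysis and gluconeogenesis had 5 of 9 up and 2 down, the same when adjusted over the list alone (adjusted p = 0.9597 with an estimated correlation). Its median of 0.62 turned to -0.78 with library totals and -0.67 on TPM, and camera's direction was down. The largest fall without a symbol was in TES1_RS04195, from 101 ± 33.3 to 7.66 ± 1.81 CPM.

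Genes of amino acid synthesis went both ways on formate. The lysine synthesis gene lysW fell from 48.8 ± 7.79 to 11.4 ± 3.24 CPM (-2.08 ± 0.25). In the list 6 of 24 rose and 7 fell, the same when adjusted over the list alone (adjusted p = 0.8648 with an estimated correlation). Amino group transfer had 3 of 6 up and 2 down, also when adjusted over the list alone (adjusted p = 0.8648 with an estimated correlation), with a median of 0.70 that turned to -0.73 with library totals and -0.58 on TPM. The nucleotide gene carA fell 4.66-fold, in a list with 1 of 7 up and 1 down (1 and 1 adjusted over the list alone; adjusted p = 0.7915 with an estimated correlation). Sulfur and iron-sulfur genes had 2 of 14 up and 6 down, the same when adjusted over the list alone, and passed downward (camera adjusted p = 0.01777; adjusted p = 0.1705 with an estimated correlation; 0.1181 without tryptone replicate 1 and 0.07751 with library totals). The sulfur and iron-sulfur falls include those of shyB, shyC, shyD and shyA, and the rises those of fdhD and surR. The call of that list is therefore not a result separate from the fall of shyBCDA. Peptidases had 3 of 6 up and 2 down, the same when adjusted over the list alone, with a median of 0.12 that turned to -1.30 with library totals and -1.18 on TPM (adjusted p = 0.9139 with an estimated correlation).

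Ribosomal protein genes rose on the TMM scale, 15 of 24 with 0 down and 15 adjusted over the list alone, with a median of 1.24 that turned to -0.21 with library totals and -0.09 on TPM (camera adjusted p = 0.01208; adjusted p = 0.7915 with an estimated correlation). Their call was lost without maltose replicate 3 (0.05785). An example is rpsE, from 502 ± 91.3 to 2349 ± 612 CPM (adjusted p = 0.001872). RNA polymerase had 1 of 5 up, rpoA2 by 3.72-fold (1 adjusted over the list alone; adjusted p = 0.8394 with an estimated correlation), and its median of 0.64 turned to -0.77 with library totals and -0.65 on TPM. Aminoacyl-tRNA synthetases had 4 of 13 up and 1 down, the same when adjusted over the list alone (adjusted p = 0.7915 with an estimated correlation); metG rose 4.08-fold and leuS 3.74-fold, while the median of 0.42 turned to -0.97 with library totals and -0.88 on TPM.

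In total 1217 of 2083 genes changed between formate and maltose, 647 up and 570 down, and 717 of them by at least 2-fold. The split was 112 up and 1531 down with library totals and 128 up and 1441 down with limma on TPM. Of the 31 lists 8 passed, 4 up and 4 down, and 0 passed with an estimated correlation. Those 8 were the 2 fdhF runs, the 2 mbhE runs, shyBCDA, the nuoI run, ribosomal protein and sulfur and iron-sulfur. The last of these also holds the shyBCDA genes. Every other list named on formate against maltose did not pass.

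Hydrogenase and formate genes changed on formate against tryptone too. The fdhF gene TES1_RS07825 rose from 3150 ± 2403 to 29880 ± 10470 CPM (3.25 ± 0.58, adjusted p = 4.478e-04), the summed hycE rose 10.4-fold, mnhG (TES1_RS07765) 11.2-fold and TES1_RS07775 25.4-fold. All 17 genes of the run rose (17 adjusted over the list alone; median 3.84, adjusted p = 0.2118 with an estimated correlation). The gene shyC fell from 226 ± 19.1 to 28.1 ± 3.07 CPM (-3.01 ± 0.21, adjusted p = 4.795e-07), with shyB, shyD and shyA also down (-2.71, -2.70 and -2.35; 4 of 4 adjusted over the list alone; adjusted p = 0.06745 with an estimated correlation). The fdhF gene TES1_RS00480 fell 4.65-fold with all 16 genes of its run (16 adjusted over the list alone; adjusted p = 0.6566 with an estimated correlation; camera adjusted p = 0.06098 with library totals). The nuoI run had 13 of 14 up (13 adjusted over the list alone; median 1.85, adjusted p = 0.6566 with an estimated correlation). The mbhE TES1_RS07645 run had 14 of 21 down (14 adjusted over the list alone; median -1.37, adjusted p = 0.2314 with an estimated correlation). The mbhE TES1_RS07715 run had 4 of 14 up and 0 adjusted over the list alone (adjusted p = 0.6566 with an estimated correlation), with a median of 0.83 that turned to -0.14 with library totals. That call was lost without tryptone replicate 2 (0.05538), tryptone replicate 3 (0.09642) or formate replicate 2 (0.0585), and 14 genes rose without tryptone replicate 1.

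Other large rises on formate over tryptone were ppsA, for phosphoenolpyruvate synthase, from 3108 ± 2651 to 23180 ± 10240 CPM (2.90 ± 0.64, adjusted p = 0.001767), metG, from 637 ± 58.2 to 3904 ± 718 CPM, and the thermosome gene thsB (TES1_RS04945), up 5.98-fold. The gene TES1_RS06220 rose 28.7-fold. Glycolysis and gluconeogenesis had 7 of 9 up and 1 down, the same when adjusted over the list alone (median 1.25, camera adjusted p = 0.03458; adjusted p = 0.6566 with an estimated correlation; 0.05453 without tryptone replicate 3). Ribosomal protein genes had 19 of 24 up and 21 adjusted over the list alone (median 1.26, adjusted p = 0.6566 with an estimated correlation). The cobalamin gene cobS fell from 871 ± 758 to 33.1 ± 2.74 CPM (-4.72 ± 0.49, adjusted p = 8.132e-06), with cbiB, cobZ and cobT also down (-4.44, -3.93 and -3.80). These were -3.72 for cobS, then -3.36, -2.91 and -2.89 without tryptone replicate 1. The arginine and pyrimidine genes argH and carA fell 11.3-fold and 10.7-fold, and TES1_RS03685 and TES1_RS03690 fell 35.2-fold and 28.8-fold; without tryptone replicate 1 the log2 fold changes of these 4 were -2.97, -3.14, -4.52 and -4.08. Cofactor biosynthesis had 3 of 16 up and 10 down, the same when adjusted over the list alone (median -1.26, adjusted p = 0.1606 with an estimated correlation).

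In total 1217 genes changed between formate and tryptone, 629 up and 588 down, and 710 of them by at least 2-fold. The split was 130 up and 1388 down with library totals and 165 up and 1105 down with limma on TPM. Without tryptone replicate 1 the count was 1555, with 878 up and 677 down. Of the 31 lists 15 passed, 5 up and 10 down, and 0 passed with an estimated correlation.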

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

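The correlation test of a wrong label and the count of genes above all other libraries were chosen after the results were seen; the mixing shares and the thinned depth were written before.

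Hydrogen was related to 7 gene lists differently on tryptone than on maltose, by a test of the difference itself, and 0 of 31 passed with an estimated correlation (adjusted p = 0.893 for each of the 7). Ribosomal protein genes had a median contrast of -1.85 (-1.19 without tryptone replicate 1). The RNA polymerase list, which also holds nusG, tfb and tfe, had -1.61 (-0.74). The run of mbhE TES1_RS07715 had -0.90 (-0.18, where it no longer passed, adjusted p = 0.572). The run of fdhF TES1_RS00480 had 0.88 (0.43), the run of mnhG TES1_RS06320 0.43 (0.35), the run of mnhG TES1_RS07205 0.43 (0.29) and amino acid biosynthesis 0.41 (0.32). With library totals and on TPM the medians were -0.96 and -0.91 for ribosomal protein, -0.68 and -0.60 for RNA polymerase, -0.04 and -0.03 for the run of mbhE TES1_RS07715 and 1.15 and 1.94 for the run of fdhF TES1_RS00480. They were 0.91 and 1.14 for the run of mnhG TES1_RS06320, 0.91 and 1.19 for the run of mnhG TES1_RS07205 and 0.93 and 1.15 for amino acid biosynthesis. With library totals the run of mbhE TES1_RS07715 (camera adjusted p = 0.07004), the run of mnhG TES1_RS06320 (0.1021), the run of mnhG TES1_RS07205 (0.1303) and amino acid biosynthesis (0.1242) did not pass. No single gene passed edgeR's test of this difference, with 403 at an unadjusted p under 0.05 and 209 called by DESeq2. The mbhE contrast also did not pass without maltose replicate 1 (-0.74, adjusted p = 0.1446), maltose with hydrogen replicate 3 (-0.95, 0.07377) or tryptone with hydrogen replicate 1 (-0.76, 0.09066). Amino acid biosynthesis did not pass without maltose replicate 3 (0.31, 0.2075). The run of mnhG TES1_RS07205 did not pass without maltose replicate 3 (0.27, 0.08256) or maltose with hydrogen replicate 1 (0.30, 0.06694). The run of mnhG TES1_RS06320 did not pass without maltose replicate 2 (0.36, 0.06861) or 3 (0.23, 0.1627), maltose with hydrogen replicate 1 (0.38, 0.06694), tryptone replicate 2 (0.44, 0.06014) or tryptone with hydrogen replicate 2 (0.38, 0.06229).

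Tryptone replicate 1 stood apart from the other tryptone libraries, with r of 0.855 to 0.896 to them, and leaned toward formate. A formate library under a wrong label is argued against by its highest correlation with a formate library, 0.86, below the lowest among formate libraries, 0.964. A first test, on log2 CPM, had put it 0.65 of the way to formate over 352 genes lower on formate and decided nothing. Over 417 genes higher on formate it stood 0.63 of the way. The correlation was taken up after that first test. Formate RNA mixed into tryptone replicate 1 as its only difference is argued against by 23 genes, cobS, cobZ, cbiB and gdhA among them. These stood at least 1.5 times above every other tryptone and formate library (1 and 0 such genes for replicates 2 and 3). Of the 23, 19 lie in the neighbourhood TES1_RS05040 to TES1_RS05315, so they are not separate pieces of evidence. They do not exclude mixing beside another difference. For other genes mixing is argued against by the shares of the formate difference reached in share of counts. These were 88.2% for genes lower and 8.4% for genes higher on formate, 79.8 points apart. Lower depth is argued against by replicates 2 and 3 thinned to the total of replicate 1, which still correlated at 0.991. A difference in the growth state of that culture may be the source and stays untested, since the labels give no growth data.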

How the results depend on the processing

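Of the alternatives for the medians of lists past the threshold, 433 kept direction and side, 152 kept direction but did not pass and 2 reversed. Over all lists, 71 of 186 medians took the other sign under some scaling. For the genes followed by name the numbers were 1566, 179 and 4, with 12 newly past, but these genes were chosen after the values were seen. Over all 283 pairs of gene and comparison past the threshold that could have been named, 4023 alternatives kept both, 505 did not pass and 123 reversed, in 47 pairs. Among the lists past the threshold and the genes followed, reversals came with library totals: ribosomal protein on formate against maltose, -0.21, the run of mbhE TES1_RS07715 on formate against tryptone, -0.14, hypF (TES1_RS07220) on formate against maltose, -0.26 (-0.13 with limma on log2(TPM + 1) and on log2(TPM + 0.1)), and surR (TES1_RS03140), -0.038. These scalings leave the median gene far below 0 on formate; otherwise the cause was not tested.

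Counts of changed genes are given in the order maltose with hydrogen, tryptone with hydrogen, difference of the responses, tryptone against maltose, formate against maltose, formate against tryptone, where they left the 1.5-fold range. With library totals the first was 31 and the third 16; with DESeq2 factors in edgeR the third was 1. DESeq2 gave 86, 290, 209 and 304. Limma on log2(TPM + 1) gave 26 for the first and 17 for the third, and log2(TPM + 0.1) the same 26 and 17. Voom, added later, gave 108, 568, 219 and 1081. With only the groups compared the second was 0 (275 unadjusted), the third 1, the fourth 6 and the last 787, with fewer libraries to estimate the spread. A 2-fold minimum left 717 and 710 on formate. The cause was not tested for the other settings.

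Leaving out 1 library gave 0 to 74, 0 to 331, 0 to 118, 41 to 220, 1025 to 1435 and 903 to 1555 genes in the same order. The second was 0 without each replicate with hydrogen, where edgeR had 323 to 380 genes unadjusted. Lists past the threshold ranged from 4 to 8, 2 to 11, 5 to 8, 8 to 16, 7 to 9 and 10 to 15. All 31 lists failed with an estimated correlation in each comparison, 0 past. Fry gave 2, 2, 0, 21 and 26 in the comparisons other than tryptone against maltose. Library totals gave 4 lists with hydrogen on maltose. Genes shared by the hydrogen responses were 3, but 16 with library totals, 21 with DESeq2 and 41 with voom, and 0 to 15 without 1 library.

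The replicate number as a block gave 25 genes and 4 lists for tryptone with hydrogen and 0 shared genes. The labels do not say that numbers pair libraries: 9 of 30 correlations between same-numbered libraries were over 0.1, and 6 libraries correlated best with their own number. It moved no other count of changed genes or of lists beyond 1.5-fold.

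No filter removed no gene and tests nothing. Removing rRNA and tRNA was not run because the files hold none. At the depth of the formate libraries 17.1% to 21.7% of simulated 1.5-fold changes were recovered.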

Other observations

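The splits of the libraries and the tests of shared reads, of formate RNA in the hydrogen libraries and of library scaling were chosen after the results were seen; those of the most abundant genes and of coding length were written before.

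None of 7 further function lists passed on formate against maltose, though members changed. Camera's adjusted p was 0.352 for chaperone and proteasome, 0.4151 for metal transport, 0.1766 for CRISPR, 0.4518 for transcription regulators, 0.7009 for antiporters, 0.7792 for DNA replication and repair and 0.4518 for mobile and toxin. In chaperone and proteasome 4 of 7 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.7915 with an estimated correlation), with a median of 0.79 that turned to -0.57 with library totals and -0.56 on TPM; thsB (TES1_RS04945), a thermosome subunit, rose from 1727 ± 643 to 6206 ± 2519 CPM. In metal transport 3 of 5 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.7915 with an estimated correlation), with a median of 0.68 that turned to -0.76 with library totals and -0.58 on TPM. The iron gene feoB rose from 555 ± 66.3 to 2247 ± 88.5 CPM (2.02 ± 0.36, adjusted p = 4.244e-04) and the tungstate gene wtpA 3.56-fold, while nikC for nickel fell 2.56-fold. In CRISPR 5 of 8 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.7915 with an estimated correlation), with a median of 1.26 that turned to -0.15 with library totals and -0.03 on TPM; cas5b rose 3.04-fold and cas7i 2.84-fold, and cas6 (TES1_RS05450) fell 1.88-fold. Among transcription regulators 4 of 6 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.7915 with an estimated correlation), with a median of 1.06 that turned to -0.34 with library totals and -0.22 on TPM; surR, which senses sulfur, rose 2.55-fold on the TMM scale and was at -0.038 with library totals. Antiporters had 3 of 7 up and 3 down, 4 down adjusted over the list alone (adjusted p = 0.8648 with an estimated correlation), and a median of -0.63 while the mean was 0.45 and camera's direction up. DNA replication and repair had 3 of 14 up and 2 down, and mobile and toxin 1 of 4 up, the same when adjusted over the list alone (adjusted p = 0.8648 and 0.7915 with an estimated correlation), and both medians turned negative with library totals, to -1.18 and -1.09, and negative on TPM.

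By share of counts the median gene stood at -1.33 on formate against maltose. Coding length as the cause is argued against by its 5 classes, whose medians ran from -1.52 to -1.1. The 50 genes with the most counts took 47.4% to 56.0% of counts on formate and 21.4% to 23.2% on maltose. Without them the median was -0.66. Leaving them out scales all other genes of a library alike, so this move follows from the shares just given and supports no cause. The value lies between the bounds set, so the test as written does not decide whether those genes account for the shift. By share of counts they account for part of it, and a median of -0.66 remains without them. A difference between the growth conditions may add to the shift and was not tested.

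The run of fdhF TES1_RS07825 was higher with hydrogen. On maltose, reads shared with the run of fdhF TES1_RS00480 are argued against by that run's median of -0.43 against 1.82. On tryptone its median of 0.46 against 1.67 lies between the bounds set, so shared reads stay open there with all libraries. Without tryptone replicate 1 the medians were 0.01 and 2.32, past the bound set against shared reads, which argues against them in that fit. On formate against maltose these runs moved apart, with medians of -2.35 and 5.00. Library scaling is argued against by medians of the run of fdhF TES1_RS07825 of 1.64 on maltose and 2.30 on tryptone with library totals. Formate RNA mixed into the hydrogen libraries was tested first on 8 genes outside the run that were at least 4-fold higher on formate, which reached 6.1% of the formate difference on maltose against the run's 23.9%, and 4.7% against 56.2% on tryptone; the 8 genes fell short of a minimum of 10 that the calculation required but the written test did not name, and genes at least 4-fold lower on formate were taken afterwards. On tryptone those 477 genes reached -60.7% (-13.8% without tryptone replicate 1), which argues against mixing. On maltose 494 genes reached 20.7% (quartiles 10.2% to 30.6%), near the run's share, as mixing would give. Mixing would also give 1 common share, but single genes of the run reached 14.5% to 100.1%. With library totals the medians of the nuoI and mbhE TES1_RS07715 runs were 1.14 and 0.99 on formate against maltose. With hydrogen on maltose they were 0.06 and -0.17. Mixing in the share of the 494 genes would raise these runs only slightly. So small a rise was not set against the spread between libraries, so these medians decide nothing. The 494 genes go with mixing, so it stays open on maltose. A response of the run to hydrogen also stays open, untested apart from these values.

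The 6 libraries of a comparison allow 10 splits, the real one included, too few for a share under 0.05. The real split, 1 of 10 in each case, gave 7 genes for maltose with hydrogen (highest other 0), 76 for tryptone with hydrogen (1), 163 for tryptone against maltose (119, with maltose replicates 1 and 2 and tryptone replicate 1 together), 1217 for formate against maltose (0) and 1217 for formate against tryptone (306, with tryptone replicate 1 beside formate replicates 1 and 3). For the difference of the hydrogen responses the real grouping gave 0 genes (highest other 1), so all 100 of 100 drawn splits give as many whatever the data, and this says nothing about chance.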
